A study of Homo sapiens with 12 samples.

How the data were processed

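BEAS-2B cells without treatment and after 72 h with nickel chloride were profiled by ChIP-seq for H3K4me3, H3K9ac, CTCF, H3K9me2 and H3K27me3, with 1 library per target and condition. The labels' protocols describe formaldehyde crosslinking, sonication, and Illumina TruSeq libraries. The 12 samples also include 2 input libraries, which have no list of regions here and entered no comparison. Samples were grouped by their titles. One label field of the H3K9ac samples names the antibody target differently from their titles and the protocol, and the titles were followed.

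The submitters' processing notes name CASAVA 1.8.2, FastQC, Bowtie 1.0.0, MACS 1.4.2 and the genome build hg19, without stating the role of each. The H3K4me3, H3K9ac and CTCF lists hold peaks whose names in the deposited lists carry the MACS prefix. The H3K9me2 and H3K27me3 lists hold broad domains from RSEG, a caller known here only from the file naming, with a version not given in the sources used here. Whether the inputs served as background, the thresholds, and the treatment of duplicate reads are also not given in the sources used here. Each list was called on 1 library. The only measurement in each list is the authors' score per peak or domain, used as deposited, with no stated normalization. Scores ranked or filtered regions within a list and were never compared between lists. Because each list was called separately, a region in 1 list only can lie just under the calling threshold in the other, and a difference in read depth, background or enrichment between libraries changes how much is called. ChIP-seq reads amplified by PCR are not independent molecules, so intervals cover counting error only.

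All regions on chromosomes 1 to 22, X and Y were used, and 0 regions were left out. Touching domains were joined. H3K9me2 bounds fall on 20 kb steps and H3K27me3 bounds on 5 kb steps, which limits how finely an edge can be placed. A peak had a partner if a peak of the other condition overlapped it by at least 1 bp. Gained and lost domain length was computed by base. An edge of a control domain that any nickel domain overlapped was counted as extended or retracted if the outermost overlapping nickel domain reached at least 10 kb beyond it or stopped at least 10 kb short. Peaks were placed in gained, kept and lost stretches and near edges (within 10 kb) by their midpoints. Shares of H3K4me3 peaks in domains of the same condition counted overlapping peaks instead, which gave higher counts than midpoints.

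Placement was described with 1000 circular shifts along each chromosome (seed 20). Shares of unmatched peaks were set against 10000 draws of as many peaks from the stated pool, matched on 10 score groups, and for H3K9ac away from H3K4me3 also on width. Percentiles among shifts and draws describe these libraries and are not tests between conditions. Shares carry exact (Clopper-Pearson) 95% binomial intervals. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were tested on simulated lists. Of peaks removed from the H3K4me3 list, 200 of 200 were found missing. For each domain mark, 50 of 50 extended edges and 50 of 50 removed domains were recovered. The planted extensions ran into free space, so domains joined across gaps were not simulated. In 20 runs each, random CTCF positions fell outside the middle 90% of shifts 3 times. H3K9ac loss that depended on score alone fell outside the middle 90% of draws 1 time. These runs used fewer shifts and draws than the analysis, and the random positions lacked the clustering of real CTCF peaks.

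The main comparisons, the rule for named regions and most other settings were fixed before the data were examined. The text names the 3 longest gained and 3 longest lost stretches of each domain mark and the 3 highest-scoring peaks of each peak target in 1 list only. The longest domains, single chromosomes, and the split of H3K9ac peaks by H3K4me3 were chosen after the data were seen. Other comparisons were also not among those fixed beforehand. These were the filling of gaps, peak densities in H3K9me2 and H3K27me3 stretches, and the overlap of the 2 domain marks. They also include CTCF peaks by edge move, CTCF loss in stretches, active peaks at H3K9me2 edges, and all peaks at H3K27me3 edges. Other settings fixed beforehand were a score minimum of 100 for the queried list or both lists, lists of equal length, overlap of 50% of the shorter peak, partners or merging within 1 kb, domains of at least 20 kb, gaps under 20 kb joined, chromosomes 1 to 22 only, edge shifts of 5 and 50 kb, and edge windows of 5 and 50 kb. Settings added after the data were seen were H3K9me2 domains of at least 100 kb, gaps up to 100 kb joined, lists without 1 Mb windows holding at least 100 CTCF peaks, the share of the length that could gain or lose H3K27me3, and other definitions of H3K9ac peaks away from H3K4me3. Planned counts of promoters and of gene lists by mark were not analysed here, because they need an hg19 gene annotation and the gene table at hand is for GRCh38.p14. For the same reason no gene is named and regions are given by coordinate.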

Results

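The series profiled chromatin in BEAS-2B cells, an immortalized human bronchial epithelial line, without treatment and after 72 h with nickel chloride, to ask how histone modifications and CTCF binding differed after exposure. The labels list the concentration as 500 mM, a level that cultured cells do not survive, so its unit is in doubt, and the processed lists cannot check it. Chromatin immunoprecipitation with sequencing (ChIP-seq) was done for 5 targets. H3K4me3 and H3K9ac mark active promoters and other active elements, CTCF is a DNA-binding insulator protein, and H3K9me2 and H3K27me3 are repressive modifications that form broad domains. Each target had 1 library per condition, so no difference between conditions has a replicate check and no p-value is given. The lists held 19276 control and 18653 nickel peaks of H3K4me3, 24311 and 18132 of H3K9ac, and 31270 and 32290 of CTCF. They held 2461 and 1298 domains of H3K9me2 and 3796 and 4001 of H3K27me3. Read numbers per library are not given in the sources used here, so depth is unknown, and exact binomial 95% confidence intervals (CI) cover counting error over regions only. Positions are 1-based on hg19, and "lost" and "gained" mean called in the control list only and in the nickel list only.

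H3K9me2 was called as fewer and longer domains in the nickel list. The number of domains fell by 47.3%, from 2461 to 1298, while their summed length went from 1391 to 1473 Mb. The count depends on short gaps: with gaps of up to 100 kb joined in both lists, it went from 1643 to 1027. Their median length changed less than the longest domains, from 280 to 320 kb. Of the control length, 1108 Mb was also covered after nickel, 282.6 Mb (20.3%) was lost, and 364.5 Mb (24.8% of the nickel length) was gained. The longest domain measured 10.2 Mb in the control list, at 5:22200001-32380000, and 26.9 Mb in the nickel list, at 3:168280001-195200000. The other long nickel domains lay at 13:86920001-112360000 (25.4 Mb) and 5:155180001-175340000 (20.2 Mb). These 3 nickel domains spanned 20, 8 and 10 control domains, and 94.9%, 98.7% and 97.1% of their length was already covered in the control list.

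**Figure D1:**
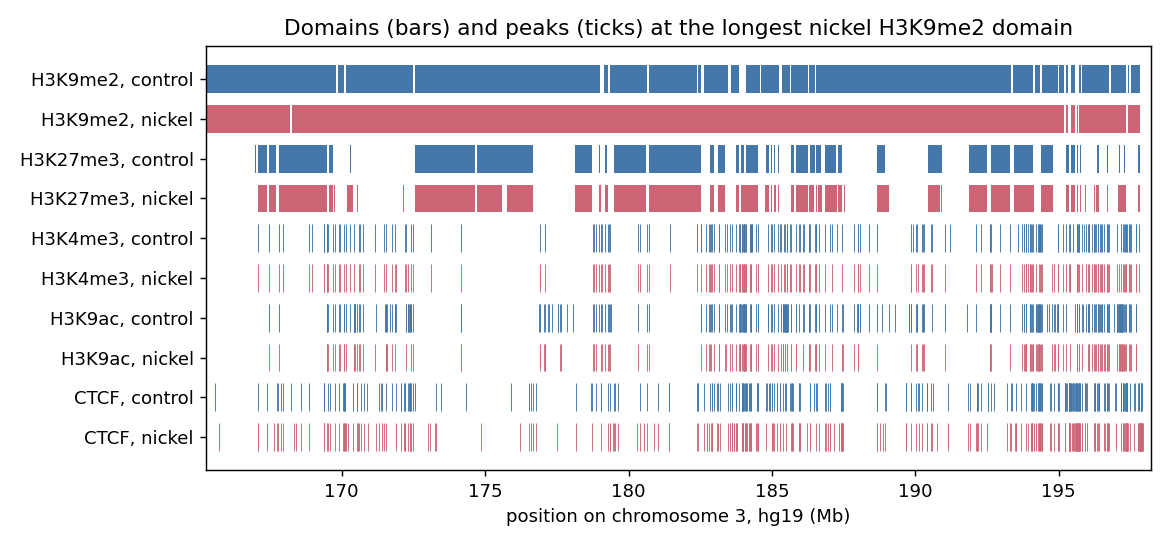
Map of the longest nickel H3K9me2 domain and its flanks on chromosome 3, with position in Mb (hg19) on the horizontal axis and 1 row per target and condition; bars are called domains and ticks are peak midpoints. The nickel H3K9me2 domain from 168280001 to 195200000 runs over the gaps between 20 control domains.

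Many gaps between H3K9me2 domains were filled after nickel. Of the 2437 gaps between control domains, 1197 (49.1%) were fully covered after nickel, while 115 of the 1274 nickel gaps (9.03%) were fully covered in the control list. Among control gaps of up to 100 kb, 572 of 818 were filled, and among those over 500 kb, 58 of 490. In all, 411 nickel domains spanned 2 or more control domains and 103 spanned 5 or more, with a maximum of 21. Of the 4182 outer edges of control domains that a nickel domain overlapped, 3053 (73.0%) were passed by at least 10 kb, 438 (10.5%) retracted by at least 10 kb and 691 stayed within 10 kb. The outermost nickel domain ended a median of 1040 kb beyond an extended edge, a distance that also runs over neighbouring control domains. The newly covered stretches themselves had a median length of 120 kb. With gaps of up to 100 kb joined in both lists, an alternative added after the data were seen, 1943 edges were passed and 404 retracted.

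The longest gained H3K9me2 stretches held more active peaks than the longest lost stretches, which held few. The gained stretch at 1:149900001-151680000 (1.78 Mb) held 46 control and 45 nickel H3K4me3 peaks, and 61 control and 49 nickel H3K9ac peaks. The other long gains were 2:203060001-204420000 (1.36 Mb, 10 H3K4me3 peaks in each list) and 14:61220001-62500000 (1.28 Mb, 13 in each list). Long losses lay at 12:125620001-131260000 (5.64 Mb), 7:66800001-72020000 (5.22 Mb) and 8:138220001-141300000 (3.08 Mb). They held 2, 0 and 2 control H3K4me3 peaks.

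The share of a chromosome under H3K9me2 differed widely between chromosomes in both conditions. Chromosome 17 went from 59.1% to 78.9% covered, chromosome 13 from 58.9% to 70.1% and chromosome 14 from 8.91% to 19.9%. Coverage went down on chromosome 19, from 24.9% to 10.9%, on chromosome 16, from 13.8% to 5.60%, and on chromosome 8, from 41.6% to 33.5%. These 6 chromosomes were picked after the values were seen.

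**Figure D2:**
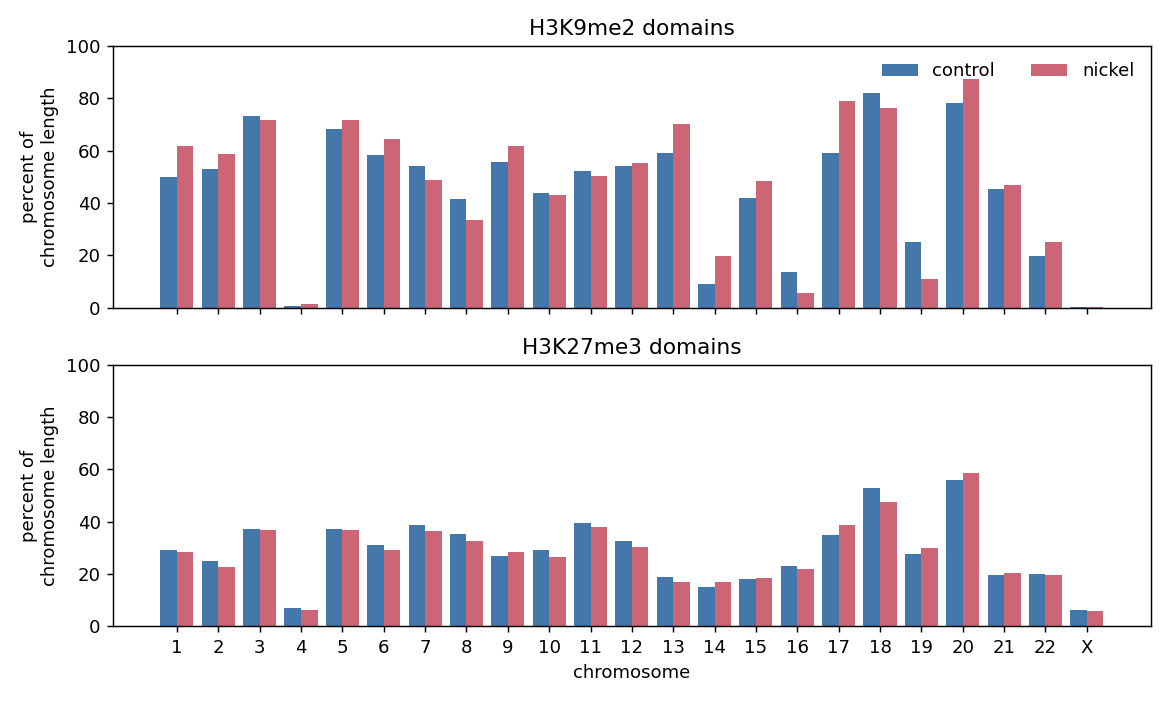
Percent of each chromosome, up to its last listed position, covered by H3K9me2 (upper panel) and H3K27me3 (lower panel) domains, with 1 bar per condition. H3K9me2 coverage of chromosome 17 rose from 59.1% to 78.9%, and chromosomes 4 and X had almost none in either condition.

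H3K27me3 domains changed far less than H3K9me2 domains. They covered 856 Mb in control and 827 Mb after nickel, and 86.5% of the union was shared, against 63.1% for H3K9me2. The lost length was 75.1 Mb (8.77% of control) and the gained length 46.5 Mb (5.62% of nickel). Of 7076 control edges, 5455 stayed within 10 kb, 939 extended and 682 retracted. Few gaps were filled in either direction, 149 of 3772 control gaps (3.95%) after nickel and 277 of 3977 nickel gaps (6.97%) in control. The longest gains were 5:178080001-178795000 (0.715 Mb), 10:123020001-123455000 (0.435 Mb) and 17:39405001-39710000 (0.305 Mb). The longest losses were 8:113585001-114320000 (0.735 Mb), 1:72090001-72670000 (0.58 Mb) and 18:69340001-69895000 (0.555 Mb), and the last of these also lost H3K9me2 along its whole length. Counts of moved H3K27me3 edges depended on the minimum shift, with 1599 extended and 1207 retracted at 5 kb, and 372 and 202 at 50 kb.

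H3K9me2 and H3K27me3 changed in the same place over at most 16.3 Mb in any combination of gain and loss, and their overlap shrank. Stretches that lost H3K9me2 and gained H3K27me3 summed to 4.03 Mb, 1.02 times the mean of 1000 circular shifts of the H3K27me3 stretches (percentile 58.9). Stretches that gained H3K9me2 and lost H3K27me3 summed to 1.56 Mb, 0.168 times the shifted mean. Loss of both marks summed to 16.3 Mb (1.98 times) and gain of both to 4.18 Mb (0.713 times). These sums depend on how much H3K27me3 was there to change, so shares of the length that could change were added after the data were seen, with control H3K27me3 shifted along. Of the 88.5 Mb of lost H3K9me2 without control H3K27me3, 4.55% gained H3K27me3, against 2.04% on average in shifts and 3.02% at most. Of the 24.2 Mb of gained H3K9me2 with control H3K27me3, 6.44% lost it, against 8.52% in shifts (percentile 0.3). Of the 194 Mb of lost H3K9me2 with control H3K27me3, 8.41% lost H3K27me3 too, against 9.19% in shifts (percentile 26.2). Of the 340 Mb of gained H3K9me2 without control H3K27me3, 1.23% gained H3K27me3, against 2.29% in shifts and below every shift. The shifts did not match for nearness to existing H3K27me3 domains. H3K27me3 length lying in H3K9me2 domains went from 587 Mb (68.6% of H3K27me3) to 425.6 Mb (51.4%), or from 1.28 to 0.920 times the shifted means. Of the lost H3K9me2 length, 68.7% lay in control H3K27me3 domains, 2.16 times the shifted mean, while 6.63% of the gained H3K9me2 length did, 0.222 times the shifted mean.

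H3K4me3 peaks were largely kept. Of the control peaks, 1361 (7.06%, CI 6.70 to 7.43) had no overlapping nickel peak, and of the nickel peaks, 1030 (5.52%, CI 5.20 to 5.86) had no control peak. The unmatched peaks were weak by the authors' peak score, which is used here only to rank peaks within a list. Their median score was 70.3 in the control list, against 902 for matched peaks, and no peak in the upper 3 of 5 score groups of either list was unmatched. Peak width rose from a median of 2050 to 2254 bp, and summed peak length went from 43.0 to 45.4 Mb. The highest-scoring control peaks without a nickel peak were 2:192709118-192712447 (score 392.6), 17:16310138-16311055 (341.3) and 15:40803239-40804515 (334.7). The latter 2 lay in stretches that gained H3K9me2. The highest-scoring nickel peaks without a control peak were 9:97780291-97781791 (300.1), 7:47492048-47494542 (299.3) and 1:8261394-8263569 (293.9), all under H3K9me2 in both conditions. Of control peaks scoring at least 100, 277 (1.66%) lacked a nickel peak in the full list.

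In the full lists, H3K9ac showed the largest change in peak number among the peak-forming targets. Limited to scores of at least 100, H3K9ac went from 17051 to 13947 peaks (0.818 times). At that limit the CTCF change was of similar size, from 15178 to 18547 (1.22 times). The list was 25.4% shorter after nickel (24311 to 18132 peaks), and summed peak length went from 42.2 to 34.7 Mb. Of the control peaks, 5843 (24.0%, CI 23.5 to 24.6) had no nickel peak, against 838 nickel peaks (4.62%, CI 4.32 to 4.94) with no control peak. The difference was concentrated away from H3K4me3. Control H3K9ac peaks that overlapped an H3K4me3 peak of the same condition lacked a nickel peak in 10.4% of 18114 cases (CI 9.92 to 10.8), and those that overlapped none in 64.0% of 6197 cases (CI 62.8 to 65.2). In the nickel list, 14.4% of the peaks away from H3K4me3 and 3.40% of those at it had no control peak, and there the share away from H3K4me3 lay within the range of score-matched draws (mean 13.5%, highest 16.5%, percentile 87.2). Peaks away from H3K4me3 numbered 6197 in control and 2021 after nickel, and the share of H3K9ac peaks at H3K4me3 went from 74.5% to 88.9%. The contrast held against peaks of like score: 10000 draws of peaks at H3K4me3 matched on score and width lost 30.4% on average and 32.4% at most.

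**Figure D3:**
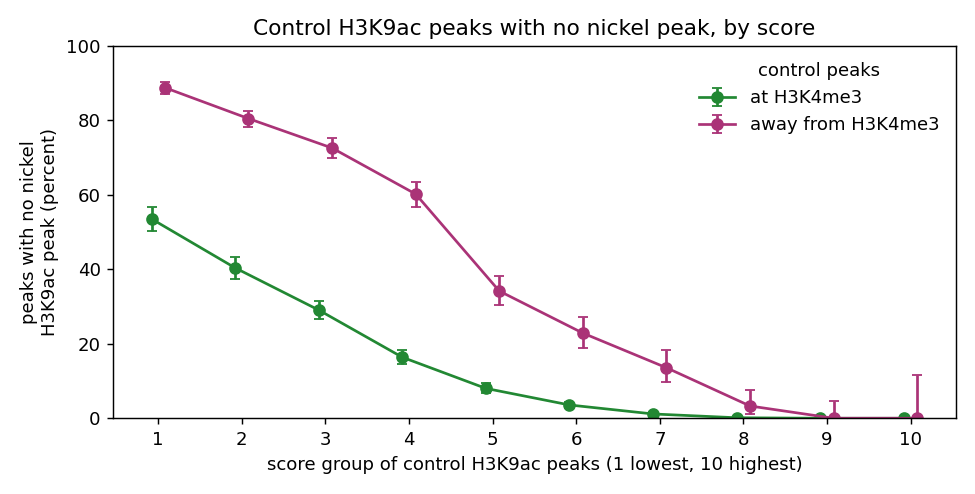
Percent of control H3K9ac peaks with no nickel H3K9ac peak (vertical axis) in 10 equal groups by control peak score (horizontal axis, 1 lowest), for peaks at and away from control H3K4me3 peaks, with exact binomial 95% intervals. In the lowest group 88.8% of the peaks away from H3K4me3 and 53.5% of those at H3K4me3 had no nickel peak, and in the highest 2 groups none of either kind.

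Among the H3K9ac peaks in 1 list only, the highest-scoring in control were 20:48920174-48924111 (score 391.1), 20:33905391-33908930 (380.1) and 5:148355932-148359524 (374.4). The first lay in a stretch that gained H3K9me2, the others under H3K9me2 in both conditions, and the first had a nickel peak within 1 kb. In the nickel list they were 4:80992702-80995004 (466.3), 7:100894431-100896214 (328.3) and 7:73082034-73083476 (286.3), none of them under H3K9me2. With the 18132 highest-scoring peaks of each list, 1848 control peaks (10.2%) and 2442 nickel peaks (13.5%) were unmatched, a setting whose equal lengths by themselves bring these counts close. Away from H3K4me3, such lists of equal length left 41.4% of 2805 control and 34.8% of 2021 nickel peaks unmatched, against 4.49% and 10.8% at H3K4me3, and of control peaks scoring at least 100, 1358 (7.96%) lacked a nickel peak in the full list.

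Gained H3K9me2 fell on stretches dense in active peaks, and those peaks mostly stayed. Control H3K4me3 peaks occurred at 14.7 per Mb in gained H3K9me2, 4.96 per Mb where H3K9me2 was called in both conditions, 1.36 per Mb in lost H3K9me2 and 5.99 per Mb elsewhere. The 5367 peaks in gained stretches were 2.12 times the mean of 1000 circular shifts of the peaks, and the 383 in lost stretches 0.196 times. Gained stretches lie outside control domains and lost stretches inside them, and the shifts did not hold this fixed. For H3K9ac the densities were 19.8, 7.36, 0.906 and 6.47 per Mb. The share of H3K4me3 peaks overlapping an H3K9me2 domain of the same condition went from 30.9% to 56.8%.

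**Figure D4:**
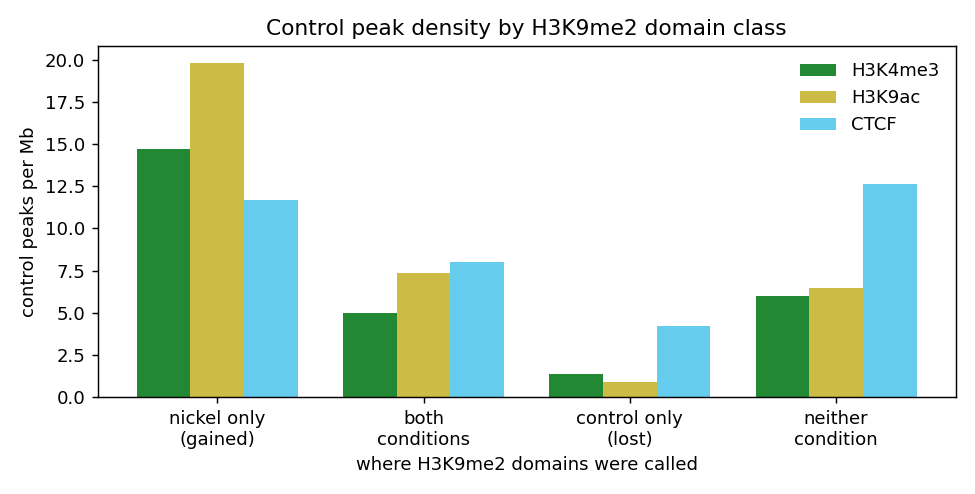
Control peaks per Mb (vertical axis) of H3K4me3, H3K9ac and CTCF in 4 classes of the genome by where H3K9me2 domains were called (horizontal axis). H3K4me3 density was 14.7 per Mb in gained and 1.36 per Mb in lost H3K9me2.

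In gained H3K9me2, 250 of 5367 control H3K4me3 peaks (4.66%, CI 4.11 to 5.26) had no nickel peak. Score-matched peaks drawn from outside H3K9me2 averaged 4.49% over 10000 draws (percentile 75.0). Where H3K9me2 was present in both conditions the H3K4me3 share was 11.1%, above the highest draw of 9.56%. H3K9ac peaks differed: 19.2% (CI 18.3 to 20.1) had no nickel peak in gained H3K9me2, against 13.2% in matched draws, and 37.4% in H3K9me2 kept in both conditions, against 19.5%. Both H3K9ac shares lay above every draw. These draws did not hold the share of peaks at H3K4me3 fixed. Drawn within peaks at H3K4me3, the shares were 8.08% against at most 6.94% in gained and 15.8% against at most 9.31% in kept H3K9me2, and within peaks away from it 60.9% against at most 54.1% and 70.1% against at most 54.5%. Limited to control peaks scoring at least 100, the shares in gained H3K9me2 were 1.26% for H3K4me3 (matched mean 0.842%, percentile 99.9) and 5.97% for H3K9ac (matched mean 3.27%).

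Full CTCF lists were similar in peak number but overlapped less than those of H3K4me3. There were 31270 control and 32290 nickel peaks, with a median width of 178 and 273 bp. Summed peak length went from 6.17 to 9.69 Mb, up 57.2%. Limited to scores of at least 100, the lists held 15178 control and 18547 nickel peaks. In control, 9638 peaks (30.8%, CI 30.3 to 31.3) had no nickel peak, and after nickel, 11607 (35.9%, CI 35.4 to 36.5) had no control peak. In the highest of 5 score groups, 24 control peaks (0.384%) and 35 nickel peaks (0.542%) were unmatched. The highest-scoring peaks in the control list only were 1:121484029-121485456 (score 1318), 14:64749329-64749722 (342.8) and 16:34190120-34190281 (306.4). In the nickel list only they were 17:34804213-34806295 (638), 17:34500254-34502187 (609.5) and 20:40363115-40363501 (581.1). The peaks on chromosomes 16 and 17 had a peak of the other list within 1 kb. A set of 32 windows of 1 Mb with at least 100 CTCF peaks in either list, defined after the data were seen, held 18.4% of control and 11.3% of nickel peaks, and 56.3% of their control peaks were unmatched against 25.1% elsewhere. The chromosome 17 peaks named above lay in such a window, 17:34000001-35000000. Of control peaks scoring at least 100, 1212 (7.99%) had no nickel peak in the full list, and 2924 such nickel peaks (15.8%) had no control peak.

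CTCF peaks, like those of H3K4me3 and H3K9ac, gathered at the edges of H3K9me2 domains in both conditions. In control, 2442 CTCF peaks (7.81%) lay within 10 kb of an edge, 2.22 times the mean of 1000 circular shifts, and after nickel 1661 (5.14%), 2.61 times. The ratios at H3K9me2 edges were 1.75 and 1.52 for H3K4me3 and 1.63 and 1.66 for H3K9ac. At H3K27me3 edges they were 2.35 and 2.19 for CTCF, 2.28 and 2.19 for H3K4me3, and 1.67 and 1.90 for H3K9ac. Control H3K9me2 edges that stayed within 10 kb carried a control CTCF peak more often than edges that moved. The share was 42.8% of 691 (CI 39.1 to 46.6), against 23.5% of 3053 extended edges and 15.8% of 438 retracted edges. The intervals treat edges as independent, although the CTCF peaks were clustered. With the CTCF peaks of the dense windows removed but all 691 stable edges kept, the share was 34.9% (CI 31.3 to 38.6). The shares at extended and retracted edges did not change, so the dense windows raised the share at stable edges only. Whether their peaks are artefacts was not tested, and no region was excluded for this beforehand. Edges inside those windows can then only count as lacking a peak, so this is not the share of edges elsewhere. The peaks were clustered, with 186 per 100 stable edges against 28.4 per 100 extended and 21.5 per 100 retracted edges. Without the dense windows there were 111 per 100 stable edges. Why stable edges carried more CTCF peaks was not tested.

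The loss of CTCF peaks at control H3K9me2 edges relative to other CTCF peaks depended on the setting. The unmatched share was 27.8% (CI 26.1 to 29.7) within 10 kb of an edge, against 28.7% in score-matched draws from elsewhere (percentile 13.6). It was 26.3% against 28.3% within 5 kb (percentile 2.79) and 28.0% against 29.5% within 50 kb (percentile 0.02). Near extended edges it was 16.5% against 24.2% matched, below every draw, and near edges that stayed it was 35.6% against 31.3%. Unmatched shares were below every draw from outside H3K9me2 in all 3 kinds of H3K9me2 stretch: 19.0% against 29.2% in gained, 25.0% against 33.1% in kept and 22.9% against 35.5% in lost H3K9me2. Leaving out the CTCF-dense windows turned the comparison at all edges, to 25.8% against 23.9% matched (percentile 98.5), while the shares were 16.5% against 21.0% near extended edges, 35.5% against 26.6% near stable edges, and 19.1% against 24.6% in gained, 23.7% against 27.6% in kept and 22.8% against 30.3% in lost H3K9me2. At scores of at least 100 the share at all edges was 8.40% against 7.67% (percentile 83.7).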

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

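Of the settings fixed before the data were examined, 69 left the main values about where they were (counts and ratios within 1.5 times, shares within their 95% interval) and 17 moved them, and of those added after the data were seen, 13 and 7. For H3K9me2, the 20 kb limits on domains and gaps and the 5 kb edge shift changed nothing because bounds fall on 20 kb steps. Those settings are counted among the 69 but say nothing about stability. Peaks scoring at least 100, set against the full other list, left 277 control and 167 nickel H3K4me3 peaks unmatched, 1358 and 132 for H3K9ac, and 1212 and 2924 for CTCF, since unmatched peaks were mostly weak. With that minimum in both lists, 3178 control H3K9ac, 2888 control CTCF and 6636 nickel CTCF peaks were unmatched. Lists of equal length left 1848 control and 2442 nickel H3K9ac peaks unmatched, counts that equal lengths bring together by construction, so they say nothing about the balance between conditions. For H3K4me3 such lists left 1022 control and 1281 nickel peaks unmatched. These counted as about the same, although their order was the reverse of that in the full lists (1361 and 1030). Away from H3K4me3, 41.4% of control H3K9ac peaks were unmatched in lists of equal length, and 69.1% with H3K4me3 peaks of either condition as the reference. Without the CTCF-dense windows (added), 6404 control CTCF peaks were unmatched, and 25.8% of those near H3K9me2 edges, now above the matched mean of 23.9%. With CTCF scores of at least 100 the share near edges was 8.40%. Joining H3K9me2 gaps up to 100 kb (added) left 1943 extended edges, as fewer edges remained. H3K27me3 edges extended 1599 times at a 5 kb shift and 372 times at 50 kb. In gained H3K9me2, unmatched shares at scores of at least 100 were 1.26% for H3K4me3 and 5.97% for H3K9ac, and 15.1% for H3K9ac with partners within 1 kb. Counted as a share of the length that could change (added), lost H3K9me2 gained H3K27me3 at 2.23 times the shifted mean and gained H3K9me2 lost it at 0.756 times. Where no construction is named, the cause was not tested. Promoter and gene list counts were not run, as they need an hg19 annotation. Read depth per library was not used here, so its share in any of these differences is open.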

Other observations

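H3K4me3 peaks overlapping H3K27me3 domains, a combination known from poised promoters, numbered 3354 in control (17.4% of H3K4me3 peaks) and 3466 after nickel (18.6%). Peaks that only reach over a domain edge are counted here. Control peaks there lacked a nickel peak in 12.4% of cases (CI 11.3 to 13.6), above the highest of 10000 score-matched draws from outside H3K27me3 (11.9%). In the nickel list the order was the other way, with no control peak for 4.36% of those in H3K27me3 domains (CI 3.70 to 5.09) and 5.79% of those outside. Broad H3K4me3 peaks of at least 5 kb went from 476 to 644, and each had a partner in the other list. CTCF peaks at H3K4me3 went from 15.1% to 17.2% of the list.

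The tests in this part were chosen after their results were seen, except the within-chromosome comparison, the matched draws of H3K9ac peaks away from H3K4me3 and the H3K9ac lists of equal length. The matched draws in gained H3K9me2 were fixed before the data were examined, but their use as a test of replacement was not.

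H3K9me2 was gained in peak-rich and lost in peak-poor stretches, with H3K4me3 densities of 14.7 and 1.36 per Mb. Gained stretches were denser than lost ones in 20 of the 20 chromosomes with at least 1 Mb of each. By construction, gained stretches lie outside control domains and lost stretches inside them. Control H3K4me3 density was already lower inside control domains (4.96 per Mb kept, 1.36 lost) than outside (14.7 gained, 5.99 elsewhere). The count therefore cannot decide on copy number of whole chromosomes, which stays open. A change of background or domain calling shared by the nickel libraries stays open. H3K27me3 stretches showed the same contrast, 7.25 times denser in gains than in losses. The same limit by construction holds there, with 3.90 per Mb in kept H3K27me3 and 7.11 per Mb elsewhere. Loss of both marks met at 1.98 times the shifted mean and gain of both at 0.713 times. As shares of the length that could change, these were 0.915 and 0.536 times. Replacement of most active peaks by H3K9me2 is argued against for each mark as a whole, since 95.3% of control H3K4me3 and 80.8% of control H3K9ac peaks in gained stretches kept a nickel peak. This does not cover the 1524 control H3K9ac peaks there away from H3K4me3. Of these, 60.9% (CI 58.4 to 63.4) had no nickel peak, and the share was higher (70.1%) where H3K9me2 was present in both conditions. Replacement of a minority stays open: 19.2% of H3K9ac peaks were unmatched against at most 14.4% in matched draws, though the share was higher (37.4%) where H3K9me2 was present in both conditions, and for H3K4me3 4.66% lay inside the range of draws (3.67% to 5.42%).

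H3K9ac peaks away from H3K4me3 lacked a partner more often than those at H3K4me3, in the control list (64.0% against 10.4%) and in the nickel list (14.4% against 3.40%). By deposited score and width, weak peaks falling under the calling threshold were not the whole cause, since matched draws lost 30.4% on average and 32.4% at most. The nickel share lay within its score-matched draws (mean 13.5%, highest 16.5%). Matching on the score of 1 library cannot equalize the underlying signal, and the median control score was 83.5 away from H3K4me3 and 235 at it. Beyond what the score captures, the explanation stays open. A shorter nickel peak list could explain part of it and stays open: with lists of equal length, control-only peaks away from H3K4me3 exceeded nickel-only ones 1.65 times (1160 and 704), between the bounds set for and against that explanation. That ratio of counts also reflects unequal sets of 2805 control and 2021 nickel peaks. As shares, 41.4% and 34.8% were unmatched. Lower enrichment in the nickel H3K9ac library and an effect of nickel on elements away from H3K4me3 both stay open and untested with 1 library per condition.

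H3K9me2 domains were nearly missing from chromosomes 4 (0.628% in control, 1.26% after nickel) and X (0.129% and 0.232%), and H3K27me3 coverage there was also low (7.05% and 6.06% in control). Chromosome Y likewise had little H3K9me2 (0.303% and 0.202%). It held 1 H3K4me3 peak per list and was left out of the comparison across 23 chromosomes. At least 585 control H3K4me3 peaks were called on each of chromosomes 4 and X, but that list comes from another library and caller. The H3K9me2 lists held 9 control and 16 nickel domains on chromosome 4 and 2 and 2 on X, so neither chromosome was left out entirely. Whether part of their reads was left out of the H3K9me2 calls cannot be told from the lists. DNA copy number of the line stays open. Across 23 chromosomes, H3K9me2 coverage rose with the median H3K4me3 score in control (Spearman 0.70, and 0.65 without the 2 chromosomes farthest from the median coverage) and less so after nickel (0.42 and 0.35). The control score was low on chromosome 4 (635), but that of X (743) was above those of chromosomes 8 (733) and 10 (729), which had 41.6% and 43.8% coverage. Chromosome 21 had the lowest score of the 23 (613) and 45.3% coverage. Chromosomes are not independent replicates, and the inputs, which would show copy number directly, were not analysed here. No biological explanation was tested.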
